A study of Mus musculus with 3 samples.

How the data were processed

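Macrophage-enriched lung cells of C57BL/6 mice were profiled by droplet single-cell RNA sequencing (10x GEM-X chemistry, 3' ends) in 3 libraries, 1 per group, each from the pooled cells of 3 mice. The groups had received PBS, LPS (4 mg/kg) or LPS with Reg3g (6 µg) in 50 µL, 24 h before the lungs were taken, per the labels' protocols. The deposited matrices hold UMI counts per gene and barcode, made with Cell Ranger 9.0.1, per the file headers and the submitters' processing notes, which also name bcl2fastq 5.0.1, Seurat 4.4.0 and the build mm10. The gene annotation is not given in the sources used here. Of 55357 features, 52081 identifiers (94.1%) matched GENCODE M21, which served for positions alone; gene symbols are those of the deposited files. The lowest barcode held 502 UMIs in the PBS library and 500 in each of the others, and no annotation of cells was used.

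Cells with at least 500 genes, at least 1000 UMIs and at most 15% mitochondrial UMIs were kept, which removed 343, 1135 and 544 barcodes of the PBS, LPS and LPS with Reg3g libraries. Doublets were taken as the highest Scrublet scores of each library, at 0.4% of barcodes per 1000 barcodes, which removed 287, 902 and 417. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 over the 3 libraries together gave 21 clusters. Clusters were called X-like from 19 marker lists fixed before the data were examined. A cluster took the class with the highest mean marker level. The scoring rule and its thresholds were set after the clusters were seen. A cluster stayed unnamed with under 3 detected markers, with 3 or more mitochondrial or ribosomal RNAs among its 10 leading genes, or with a median doublet score above 0.1. The same held for a shallow cluster with no marker among its leading genes. This left 2 clusters unnamed, 1 led by mitochondrial and ribosomal RNA and 1 with high doublet scores. No cluster was named for plasmacytoid dendritic cells, eosinophils, basophils or mast cells, erythroid cells or platelets.

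UMI counts were summed per class and library and divided by the class total, giving counts per 1e6 counts (CPM). The log2 ratio of 2 libraries has an exact conditional binomial 95% interval, a CPM an exact Poisson and a share an exact Clopper-Pearson interval. A count of 0 was replaced by a floor of 3 counts, per library, and the ratio is then a bound. With 1 library per group no p-value, standard error or number of changed genes was computed. The 21 gene lists, the rule for named genes, the contrasts and the main settings were chosen before the data were examined. A list's median covers members with at least 10 CPM in at least 1 library and was ranked among 10000 random lists of the same size and expression.

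Named genes are the 10 highest and 10 lowest log2 ratios in alveolar-macrophage-like cells (5 and 5 in other classes) among genes with at least 50 CPM in the higher library. Ribosomal protein, mitochondrially encoded, haemoglobin, immunoglobulin and predicted genes were left out, as were genes whose CPM was under 10% of that in another class of at least 50 cells of the same library. From each list up to 4 members with the largest ratios could be named as well; Reg3g and Extl3 are given throughout. Adgre1, Scgb1a1, S100a8 and S100a9 lie outside this rule and are given as signs of the sort gate, of epithelial RNA and of neutrophil RNA. The list for glycolysis and hypoxia lacked 1 symbol in the files.

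Shares of cells with a UMI were taken after thinning each cell to 2000 UMIs. The plan lowered this depth for a class where it left out too many cells. That was not done for lymphoid cells, of which 75 of 164 (PBS), 92 of 175 (LPS) and 52 of 117 (LPS with Reg3g) were left out. Lymphoid shares therefore describe the deeper cells alone. Dependence of the Reg3g contrast on the LPS contrast was measured by a slope across genes, beside a simulated unchanged group and 100 splits of the LPS cells into 2 parts. Counts were simulated from a Poisson distribution, which the interval assumes, so the check covers the calculation and not the spread between cells. For LPS against PBS (7836 genes) the interval held the known ratio for 95.1% of unchanged, 97.0% of 2-fold and 91.0% of 4-fold genes. For LPS with Reg3g against LPS (7871 genes) these values were 95.2%, 93.0% and 98.0%.

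Alternatives were another cell filter (none, or at least 1000 genes and at most 10% mitochondrial UMIs), doublet removal (none or doubled), Leiden resolution 0.5 or 2, each library clustered alone, clustering without the response lists, median-of-ratios and trimmed mean scaling, cells weighted equally, thinning, all cells of a library together, list floors of 5 and 50 CPM, and lists without possible carry-over genes. Weighting the clusters as in the LPS library, leaving out the cycling cluster and the shares of other classes were added after the data were seen. Python 3.11.15 was used with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9 and matplotlib 3.10.9.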

Results

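The series measured RNA in single lung cells of C57BL/6 mice 24 h after an instillation into the trachea of PBS, of LPS (bacterial lipopolysaccharide, 4 mg/kg), or of the same LPS dose with 6 µg of Reg3g, a secreted C-type lectin. Cells were sorted as live CD45-positive, Ly6G-negative, F4/80-positive and positive for CD11b or CD11c, a gate meant for macrophages. Each group is 1 library made from the pooled cells of 3 mice, so no difference between groups has a replicate check and no test between groups was made. The PBS library held 8475 barcodes and 52354207 UMIs, the LPS library 15015 barcodes and 70474636 UMIs, and the LPS with Reg3g library 10213 barcodes and 60942042 UMIs. After the cell filter and doublet removal 7860, 13012 and 9278 cells remained in the same order, with a median of 5924, 4218 and 5456 UMIs per cell. Intervals after values are 95% intervals that cover counting error only, not differences between mice or preparations. For CPM and ratios they also leave out the spread between cells.

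The first question is which cells the sort delivered in each group. Alveolar-macrophage-like cells were 45.4% (44.3 to 46.5) of the cells of the PBS library, 38.6% (37.7 to 39.4) of the LPS library and 44.1% (43.1 to 45.2) of the LPS with Reg3g library. Monocyte-like cells were 27.9% (26.9 to 28.9) with PBS, 46.6% (45.7 to 47.4) with LPS and 44.8% (43.8 to 45.8) with LPS and Reg3g. Interstitial-macrophage-like cells were 5.80% with PBS, 1.18% with LPS and 1.38% with LPS and Reg3g. Dendritic-cell-like cells of all 3 kinds together were 16.1% (15.3 to 16.9), 8.18% (7.71 to 8.66) and 2.74% (2.42 to 3.09), so their share with Reg3g was 2.99-fold (2.60 to 3.44) lower than with LPS alone.

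The dendritic-cell-like classes differed from each other between PBS and LPS. Type 1 conventional dendritic-cell-like cells were 8.66% of the PBS library, 2.29% of the LPS library and 0.733% of the LPS with Reg3g library. Type 2 cells were 6.06%, 1.77% and 0.539% in the same order. Migratory dendritic-cell-like cells, which carry the lymph node homing receptor Ccr7, were 1.37% with PBS, 4.12% with LPS and 1.47% with LPS and Reg3g. Neutrophil-like cells, which the Ly6G gate should remove, were 0.115%, 1.38% and 1.95%. T-or-NK-like cells were 1.25%, 1.17% and 0.992%, B-cell-like cells 0.840%, 0.177% and 0.269%, and structural cells 0.636%, 0.315% and 0.248%. Clusters that stayed unnamed held 1.99%, 2.48% and 3.45% of the cells. The smaller classes moved with the settings. Over 8 alternatives type 2 cells ranged from 1.08% to 2.37% with LPS and from 0% to 0.712% with Reg3g, and type 1 cells reached 1.70% with Reg3g when each library was clustered alone. The 3 kinds together ranged from 7.46% to 8.92% with LPS and from 2.59% to 3.14% with Reg3g. Neutrophil-like cells ranged from 0.715% to 1.83% with LPS and from 1.02% to 2.32% with Reg3g, and under the stricter cell filter they were not more with Reg3g (1.02%) than with LPS (1.11%). T-or-NK-like cells ranged from 0.694% to 2.35% with LPS, B-cell-like cells from 0% to 0.276%, and unnamed clusters from 1.30% to 6.44%.

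These shares describe what passed the sort, and F4/80 RNA (Adgre1) itself differed between the groups, with 111 CPM in alveolar-macrophage-like cells with PBS, 200 with LPS and 193 with LPS and Reg3g. The libraries also differed in depth, as the median UMIs per cell above show, and the split of monocyte-like cells into classical-like and nonclassical-like moved with the clustering (nonclassical-like from 2.00% to 19.5% of the LPS library over the alternatives against 20.1% as chosen), so the monocyte-like cells are described together.

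**Figure D1:**
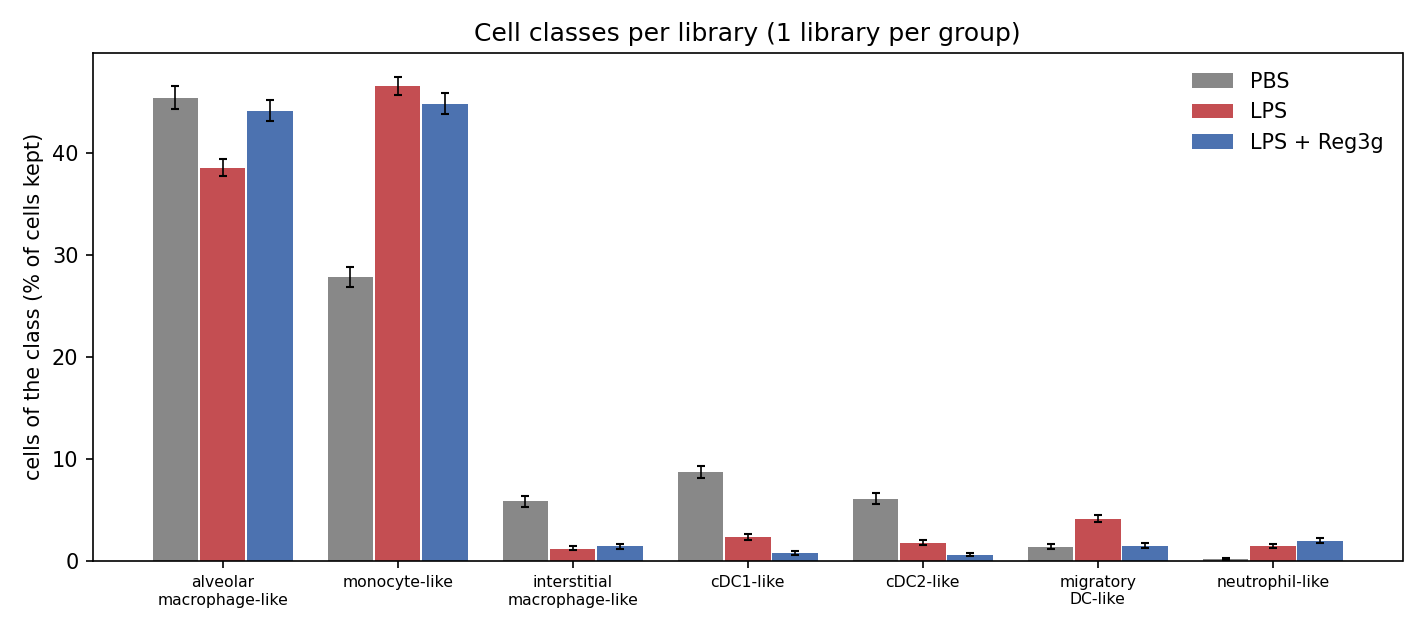
Share of each cell class (vertical axis, % of cells kept) in the PBS, LPS and LPS with Reg3g libraries, 1 library per group, with exact binomial 95% intervals of counting error. Dendritic-cell-like shares were lowest in the LPS with Reg3g library for type 1 (0.733%) and type 2 (0.539%), and the migratory share was highest in the LPS library (4.12%).

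The second question is what LPS did to the expression of alveolar-macrophage-like cells. Genes of inflammation, chemokines and the interferon response were far higher with LPS than with PBS, and genes of resident alveolar macrophage identity and of the cell cycle were mostly lower. Lcn2, an iron-sequestering antibacterial protein, stood at 0.424 CPM with PBS and 1568 CPM with LPS (log2 ratio 11.85, 11.05 to 12.81). Cxcl3, a neutrophil-attracting chemokine, stood at 6.12 and 2390 CPM (log2 ratio 8.61). Fabp1, a lipid-binding protein of resident alveolar macrophages, stood at 1287 CPM with PBS and 116 CPM with LPS, 11.1-fold lower. The gene with the lowest log2 ratio among those ranked was Tppp3, at 209 and 6.01 CPM (-5.12, -5.34 to -4.91).

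The 10 genes highest with LPS against PBS included the chemokines Ccl5 (log2 ratio 9.87) and Ccl17 (8.10), the serine protease inhibitor Serpina3g (10.90) and the collagen-cleaving protease Mmp14 (0.424 to 109 CPM). Serpina3f had 0 counts with PBS and 81.2 CPM with LPS, at least 765-fold higher against a floor of 3 counts. The others were the retinoic acid degrading enzyme Cyp26b1 (9.53), the itaconate-making enzyme Acod1 (9.34) and the cell-surface proteoglycan Sdc4 (9.27). Saa3, an acute-phase protein, was set aside because its 401 CPM in these cells with LPS is 3.59% of its level in interstitial-macrophage-like cells of that library. On the lower side stood Spp1 (osteopontin), at 573 and 32.7 CPM (-4.13), the adhesion molecule Epcam (-4.13), Gvin3 (-3.81), the secreted ribonuclease Rnase6 (-3.77), Cpne5 (-3.63), Prr5l (-3.54), the chemokine receptor Cxcr4 (-3.49) and the leukocyte actin-binding protein Lsp1 (-3.42).

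Some of these RNAs were also seen in lymphoid cells of the same library, and others hardly were. The level of macrophage genes in lymphoid cells differed between libraries. Of 25 alveolar macrophage identity genes measured there, 17 were at least 2-fold higher with LPS than with PBS and 1 lower (median log2 ratio 1.90). After thinning to 2000 UMIs per cell, Lcn2 was seen in 61.6% of alveolar-macrophage-like cells with LPS and in 42.2% of lymphoid cells of the same library, and Ccl5, which T and NK cells make, in 39.0% and 53.0%. Cxcl3 was seen in 82.7% against 20.5%, Ccl17 in 37.5% against 13.3%, Cyp26b1 in 22.7% against 1.20% and Serpina3f in 13.1% against 1.20%. Unthinned, Lcn2, Ccl5, Cxcl3 and Ccl17 were seen in 76.2%, 50.3%, 88.4% and 48.4% of these alveolar-macrophage-like cells. Median depth in the LPS library was 6047 UMIs in alveolar-macrophage-like and 1900 in lymphoid cells, and thinning left out 197 of 5017 and 92 of 175 cells. Of the 10 highest genes, 6 had a share in the LPS library whose interval lay above that of lymphoid cells; Serpina3g (31.7% against 24.1%), Acod1 (25.9% against 18.1%) and Mmp14 (17.4% against 12.0%) did not, nor did Ccl5. Of the 10 lowest genes 7 did so in the PBS library, and Gvin3 (19.9% against 12.4%), Rnase6 (16.8% against 11.2%) and Cxcr4, which lymphoid cells make themselves, did not.

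Inflammatory lists moved together. Of 14 measured chemokines 12 were at least 2-fold higher with LPS and 1 at least 2-fold lower, with a median log2 ratio of 3.87; Ccl9 (22.6 to 1589 CPM, 6.14) followed those named above. Of 27 NF-kB and LPS-inducible genes 21 were at least 2-fold higher and 0 lower (median 1.94), among them Ptges (4.87). Of 23 interferon response genes 18 were at least 2-fold higher and 0 lower (median 2.91), such as Irf7 (2.30 to 56.4 CPM, 4.62), the antiviral enzyme Rsad2 (4.43) and Ifi205 (4.99), whose low level here leaves carry-over from other cells possible. Of 7 measured inflammatory cytokines Il6 (4.66), Il1b (4.60), Il1a (4.41) and Tnf (2.93) were at least 2-fold higher, and 2 were at least 2-fold lower, with a median of 2.93. Each of these 4 medians lay at percentile 100 of 10000 random lists matched on expression, while members of a list are not independent of each other.

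The resident programme went the other way in part. Of 27 alveolar macrophage identity genes 12 were at least 2-fold lower and 4 at least 2-fold higher (median -0.54). The sialic acid receptor Siglecf stood at 124 and 12.0 CPM (-3.37), Krt19 at 408 and 40.3 CPM (-3.34) and Ear1 at 1134 and 200 CPM (-2.50). This list shares genes with the markers that named the class, and different clusters held the class in the groups. Cluster 3 held 93.7% of these cells with PBS, and clusters 1, 6 and 7 held 2789, 920 and 1156 of 5017 with LPS.

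Other lists were split. Of 21 phagocytosis and scavenging genes 5 were at least 2-fold higher, such as the integrin Itgam (4.78) and the scavenger receptor Marco (1.89), and 7 lower, such as the beta-glucan receptor Clec7a (-2.84) and the high-affinity antibody receptor Fcgr1 (-2.07), with a median of -0.60. Of 26 lipid and surfactant handling genes 4 were higher, among them the fatty acid desaturase Scd1 (3.29), and 5 lower, among them the cholesterol exporters Abcg1 (-2.09) and Abca1 (-1.77), with a median of 0.22. Of 13 alternative activation and repair genes 2 were higher and 4 lower (median -0.64), including Klf4 (-2.17). Of 11 MHC class II and co-stimulation genes 1 was higher and 4 were lower, such as H2-DMa (-2.19), with a median of -0.68. The dendritic-cell-like share was 16.1% with PBS and 8.18% with LPS, and 6 members of this list are possible carry-over from other cells. Of 16 MHC class I presentation genes 6 were higher and 0 lower (median 0.71), led by H2-Q7 (2.44).

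Of 17 glycolysis and hypoxia genes 6 were higher and 0 lower (median 0.42), led by the glucose transporter Slc2a1 (2.35) and Pfkl (1.85). Of 23 oxidative stress genes 7 were higher, such as the cystine transporter Slc7a11 (3.79), Sod2 (3.67) and the ferritin chain Fth1 (18660 to 88040 CPM), and 2 lower, with a median of 0.25. Of 18 cholesterol biosynthesis genes 2 were higher and 0 lower (median 0.47), and of 24 oxidative phosphorylation genes none differed 2-fold (median 0.11). Medians below 0 were found for inflammasome and cell death genes (-0.15; 3 higher and 1 lower of 17, led by Zbp1 at 2.59), LPS sensing genes (-0.36; 1 and 1 of 14), and autophagy and lysosome genes (-0.20; 1 and 1 of 24). The medians of the inflammasome and the autophagy list turned positive under both other scalings, and the LPS sensing median turned to 0.46 with members from 50 CPM.

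Of 23 cell cycle genes 17 were at least 2-fold lower and 0 higher (median -2.12), such as Cenpf at 31.9 and 4.11 CPM (-2.96) and Cenpe (-2.29). Cluster 16, led by cell cycle genes, held 5.60% of these cells with PBS and 1.83% with LPS, and without it the median was -0.05. With cells thinned to 2000 UMIs it was -1.33. Genes of the dissociation and immediate early response, a sign of handling, had a median of -0.88, with 7 of 18 at least 2-fold lower (Fosb -2.65, Jun -1.98) and 1 higher. The 9 mitochondrially encoded genes were lower too (median -0.95, 4 of them at least 2-fold). Scgb1a1, a club cell gene, stood at 62.9 CPM with PBS and 16.4 with LPS in these cells.

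The median of all 7873 genes measured in these cells was -0.25 for LPS against PBS under scaling to the total, 0.08 under median-of-ratios scaling and 0.09 under trimmed mean scaling. Relative to the first of these the medians were 4.12 for chemokines, 3.16 for the interferon response, 2.19 for NF-kB genes, -0.29 for alveolar macrophage identity and -1.87 for the cell cycle.

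**Figure D2:**
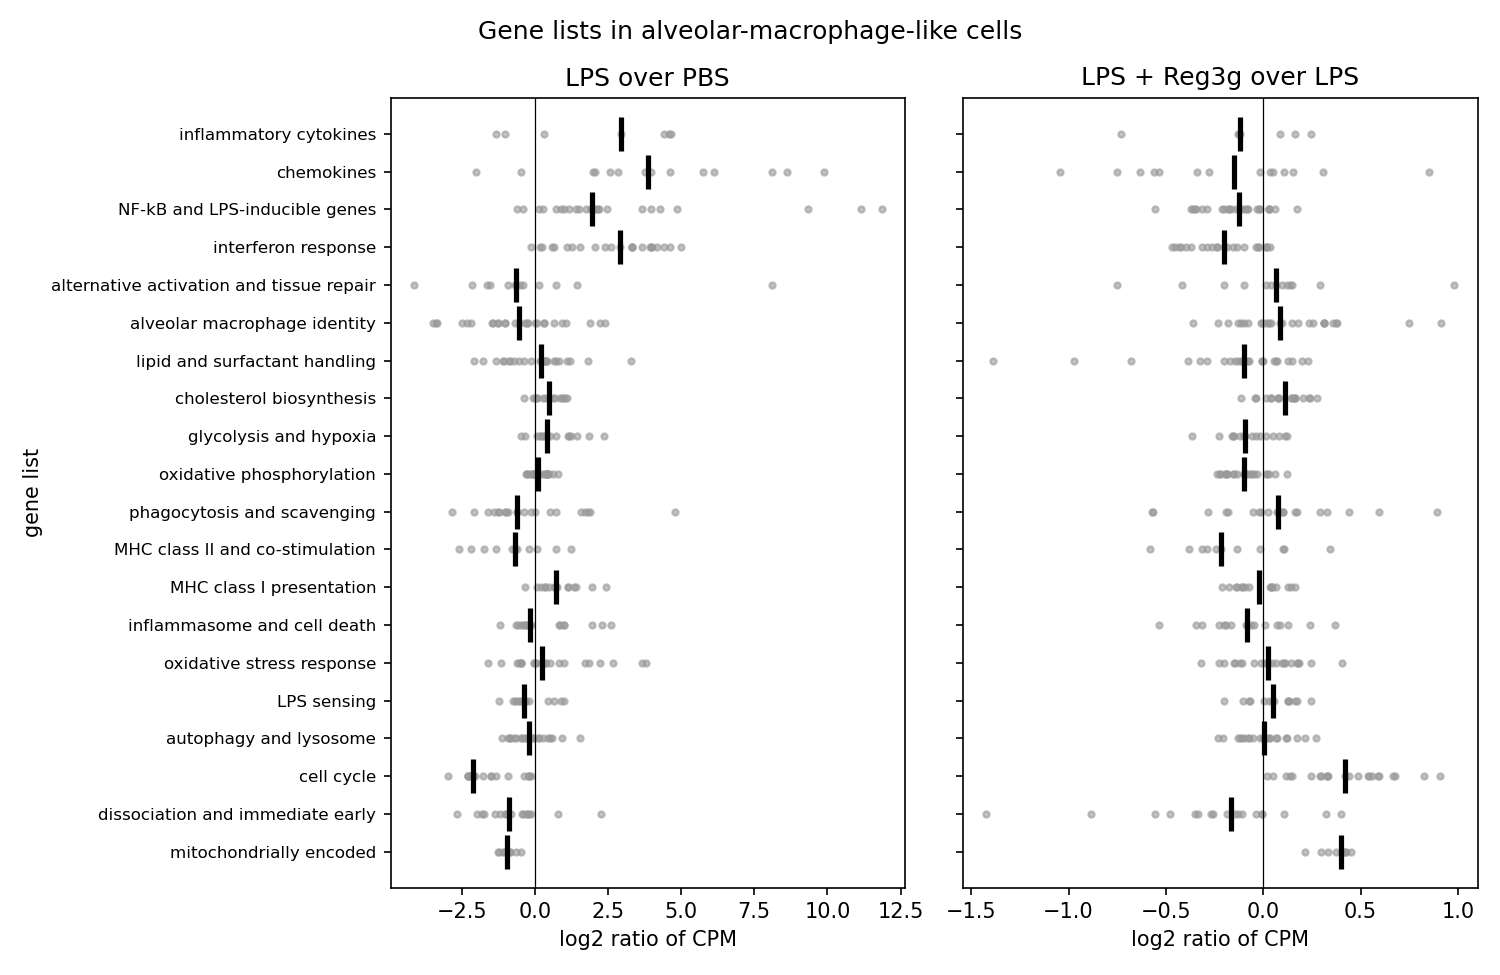
Log2 ratios of the members of the fixed gene lists (grey points) and the median of each list (black bars) in alveolar-macrophage-like cells. The panels show LPS against PBS and LPS with Reg3g against LPS, on axes of different range. The list of Reg3 ligands and receptors is not drawn. The median lay at 3.87 and -0.15 for chemokines and at -2.12 and 0.42 for the cell cycle list.

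The third question, which the title of the series raises, is how Reg3g given with LPS altered alveolar-macrophage-like cells. Differences from LPS alone were small beside those between LPS and PBS, and many had the opposite sign. Fabp1 stood at 116 CPM with LPS and 218 with LPS and Reg3g (log2 ratio 0.91, 0.85 to 0.97) against 1287 with PBS. Clec7a stood at 143 and 266 CPM (0.89) against 1024 with PBS. On the lower side Scd1, which makes monounsaturated fatty acids, stood at 50.5 CPM with LPS and 19.3 with Reg3g (-1.39, -1.53 to -1.25), and Ccl17 at 1007 and 599 CPM (-0.75, -0.78 to -0.72).

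Among the 10 genes highest with Reg3g against LPS were Spp1 (0.98), the fungal pattern receptor Clec4n (0.64), Pdlim1 (0.59), the anti-inflammatory annexin Anxa1 (0.58), Ybx3 (0.56), Trib1 (0.55), the metalloprotease Mmp19 (0.53) and Cd2 (0.52). Each of the 10 except Ybx3 was lower with LPS than with PBS. The LPS library enters both ratios, which favours this outcome, and the median of all genes for LPS against PBS was also below 0 (-0.25). Among the 10 lowest were the transcription factor Klf2 (-0.94), the lipid droplet protein Hilpda (-0.84), Fstl1 (-0.77), the platelet-activating factor receptor Ptafr (-0.67), the adenosine receptor Adora2b (-0.64), Serpina3g (-0.63), Rgcc (-0.57) and the interferon-induced chemokine Cxcl10 (-0.56). Of these 20 genes, Scd1 alone differed by 2-fold or more (2.62-fold lower). Fstl1 and Serpina3g are leading genes of cluster 7, which held 23.04% of these cells with LPS and 13.55% with Reg3g. Whether this shift of clusters accounts for their ratios was not tested. Hspa1a, S100a6, Apoe and Ccl4 were set aside because of their higher level in other cells of the library.

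Of the 10 higher genes 4, and of the 10 lower genes 5, had a share whose interval lay above that of lymphoid cells in the library where they were higher. Ybx3, Trib1, Mmp19, Hilpda, Ptafr, Serpina3g and Cxcl10 were among those that did not. In lymphoid cells 22 of 25 alveolar macrophage identity genes were lower with Reg3g than with LPS, 11 of them at least 2-fold (median log2 ratio -0.93). Background RNA may therefore differ between these libraries, and its part in the ratios was not tested. Spp1 was seen in 4.67% of alveolar-macrophage-like cells with LPS and 7.26% with Reg3g after thinning, and in 4.82% and 6.15% of lymphoid cells, so in the LPS library its share was no larger than the lymphoid share. Pdlim1 was seen in 12.4% against 13.9% with Reg3g, where it was higher. For Cd2 and Klf2, which T and NK cells make themselves, the lymphoid share gives no background. Fabp1 (16.7% and 25.4% against 6.02% and 1.54%) and Clec7a (22.3% and 34.3% against 9.64% and 9.23%) lay above the lymphoid share in both libraries. Scd1 was seen in 7.22% and 2.71% of alveolar-macrophage-like cells against 0% and 10.8% of lymphoid cells. Ccl17 was seen in 37.5% and 24.5% against 13.3% and 1.54%, and migratory dendritic-cell-like cells, which hold more of it (3294 CPM in the LPS library), were fewer with Reg3g. Unthinned, the shares with LPS and with Reg3g were 9.31% and 16.6% for Spp1, 31.2% and 47.0% for Fabp1, 43.3% and 61.7% for Clec7a, 15.3% and 8.47% for Scd1, and 48.4% and 37.5% for Ccl17. Median depth was 6047 and 7545 UMIs in alveolar-macrophage-like and 1900 and 2305 in lymphoid cells, and thinning left out 76 of 4096 and 52 of 117 cells of the Reg3g library.

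Most list medians shifted by less than 0.25 with Reg3g. Of 27 NF-kB and LPS-inducible genes 22 were lower with Reg3g than with LPS, none by 2-fold (median -0.12), including Lcn2 (1568 and 1067 CPM, -0.56) and Acod1 (-0.35). Of 23 interferon response genes 19 were lower, none by 2-fold (median -0.20), such as Gbp5 (-0.45), Gbp2 (-0.43) and Oasl1 (-0.47), the last a possible carry-over from other cells. Of 14 chemokines 8 were lower and 6 higher (median -0.15); Cxcl9 was 2.07-fold lower, and Ccl2 (0.85), a possible carry-over from other cells, was higher. Of 7 cytokines 4 were lower and 3 higher (median -0.12), with Il6 at -0.73, Il1b at -0.13 and Tnf at 0.16. The interferon median came to 0.01 with the alveolar-macrophage-like clusters weighted as in the LPS library. Gbp2 is a leading gene of cluster 7, which held a smaller part of these cells with Reg3g. The chemokine median came to 0.01 with members from 5 CPM.

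Of 27 alveolar macrophage identity genes 18 were higher with Reg3g, none by 2-fold (median 0.09), with Siglecf at 12.0 and 20.2 CPM (0.75) and Krt19 at 0.37. All 23 cell cycle genes were higher, none by 2-fold (median 0.42), such as Pclaf (0.91), Cdk1 (0.83) and Top2a (0.68). Cluster 16, led by cell cycle genes, held 92 of these cells with LPS (1.83%) and 91 with Reg3g (2.22%). Without cluster 16 the cell cycle median was 0.19. It was 0.17 with clusters weighted as in the LPS library, and -0.21 over all cells of each library. Of 26 lipid and surfactant genes 19 were lower (median -0.10), with Scd1, Apoc1 (-0.97) and Pnpla2 (-0.39) lowest among those not set aside. Of 11 MHC class II and co-stimulation genes 8 were lower (median -0.22), including H2-Eb1 (-0.58), H2-Aa (-0.38) and Cd74 (-0.32), beside the lower share of dendritic-cell-like cells, where these genes are most abundant. These 3 genes and 3 other members are possible carry-over from other cells, and without the 6 the median was -0.02. Of 21 phagocytosis genes 13 were higher (median 0.08), and of 18 dissociation and immediate early genes 15 were lower (median -0.17), among them Fos (-0.48) and, as possible carry-over from other cells, Hspa1b (-0.88). All 9 mitochondrially encoded genes were higher (median 0.40). This was not particular to these cells. The median was 0.47 in monocyte-like, 0.52 in dendritic-cell-like, 0.46 in neutrophil-like and 0.30 in lymphoid cells.

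The other lists moved little with Reg3g. Their medians were 0.11 for cholesterol biosynthesis, -0.09 for glycolysis and hypoxia, -0.10 for oxidative phosphorylation, -0.02 for MHC class I presentation, -0.08 for inflammasome and cell death (Nlrp3 -0.54), 0.02 for oxidative stress (Hmox1 0.41), 0.05 for LPS sensing, 0.00 for autophagy and lysosome, and 0.07 for alternative activation and repair. None of the genes in these 9 lists differed 2-fold. The median of all 7873 genes was 0.04.

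Reg3g itself was instilled as protein, and its RNA was near the floor, with 2, 11 and 3 counts in the alveolar-macrophage-like cells of the PBS, LPS and LPS with Reg3g libraries, and 9, 21 and 17 counts in all cells. Extl3, described as a Reg3 receptor, stood at 14.0, 14.5 and 15.8 CPM in these cells. Of the 7 genes of the list of Reg3 ligands and receptors Extl3 and Il6st were measured (median -0.91 for LPS against PBS and 0.08 for Reg3g against LPS), and Il6st stood at 61.4 CPM with PBS, 16.8 with LPS and 17.2 with Reg3g. On mm10 Reg3g (ENSMUSG00000030017) lies on chromosome 6 from 78466269 to 78468872, Extl3 (ENSMUSG00000021978) on chromosome 14 from 65052060 to 65149855, Fabp1 (ENSMUSG00000054422) on chromosome 6 from 71199827 to 71205023, Scd1 (ENSMUSG00000037071) on chromosome 19 from 44394455 to 44407879, and Lcn2 (ENSMUSG00000026822) on chromosome 2 from 32384633 to 32388252.

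**Figure D3:**
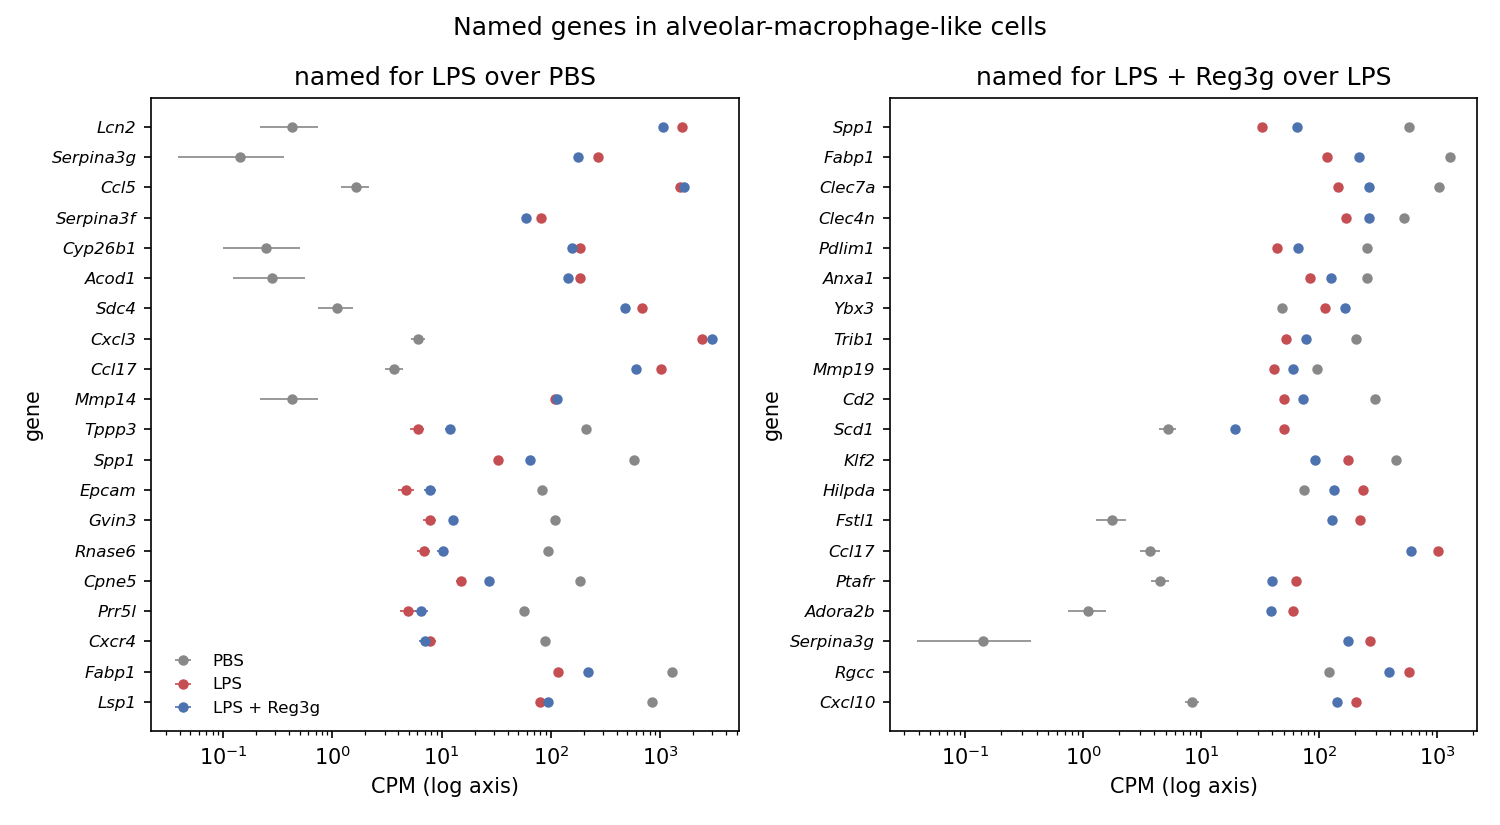
CPM (log axis) in alveolar-macrophage-like cells of the PBS, LPS and LPS with Reg3g libraries, 1 point per library, for the genes named by the fixed rule; a level of 0 is not drawn. Fabp1 lay at 1287, 116 and 218 CPM and Scd1 at 5.16, 50.5 and 19.3 CPM.

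The fourth question is how far the cells given LPS with Reg3g lay from PBS. They stayed close to the LPS state: against PBS the medians were 3.56 for chemokines (12 of 14 at least 2-fold higher), 2.53 for the interferon response (17 of 23), 1.91 for NF-kB genes (21 of 27), -0.34 for alveolar macrophage identity (8 of 27 at least 2-fold lower, 4 higher) and -1.46 for the cell cycle (16 of 23 lower). Of 389 genes at least 2-fold higher with LPS than with PBS, 77.6% were lower with Reg3g than with LPS (median log2 ratio -0.14). Of 776 genes at least 2-fold lower with LPS, 88.8% were higher with Reg3g (median 0.21). Over the 6096 genes between, 58.6% were higher and 41.4% lower with Reg3g (median 0.03). The LPS library both chose these sets and enters the Reg3g ratio, which can push the shares this way. No split of the LPS cells is given for these shares. Across 7261 genes, which are not independent replicates, the slope of the Reg3g against LPS ratios on the LPS against PBS ratios was -0.0965 (covariance -0.0822). Both ratios share the LPS library. A simulated unchanged group gave a slope of 0.000314 (covariance 0.000268), but it was drawn from the LPS profile itself. Its slope was therefore set by its design and does not show what the sharing adds. With the LPS cells split at random into 2 parts, 1 for each ratio, the slope was -0.0939 (range over 100 splits -0.102 to -0.0858), and it was -0.0497 with the clusters weighted as in the LPS library. Cluster 6 held 920 of 5017 alveolar-macrophage-like cells with LPS and 1082 of 4096 with Reg3g, and cluster 7 held 1156 and 555.

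In monocyte-like cells with LPS, Saa3 stood at 4.13 CPM with PBS and 9152 with LPS (log2 ratio 11.12), and the arginine-degrading enzyme Arg1 had 1 count with PBS and 145 CPM with LPS (10.23, 7.75 to 15.53). Upp1 (8.09), Mmp14 (7.60) and AA467197 (7.20) were the next highest. The prostaglandin-degrading enzyme Hpgd (231 to 15.1 CPM, -3.93), the growth factor receptor Flt1 (-3.85), Cd177 (-3.79), the heat shock gene Hspa1b (-3.55) and Serpinb10 (-3.50) were lowest. Hspa1b belongs to the dissociation and immediate early list, where 8 of 18 genes were at least 2-fold lower and 1 higher (median -0.95). The median of the 9 mitochondrially encoded genes was -0.46. Of 24 cell cycle genes 23 were at least 2-fold higher (median 2.62), such as Birc5 (6.80 to 73.4 CPM, 3.43) and Ccnb1 (3.87). Of 17 chemokines 12 were at least 2-fold higher (median 3.26), such as Ccl12 (6.87). Of 29 NF-kB and LPS-inducible genes 21 were at least 2-fold higher (median 1.52). Of 31 interferon response genes 4 were higher and 2 lower (median -0.10), but the subsets of the clustering as chosen differed. In its nonclassical-like cells 16 of 30 were higher and 1 lower (median 1.02), and in its classical-like cells 3 of 31 were higher and 5 lower (median -0.31). These medians were not run under other clusterings, and the split itself is unstable. Nonclassical-like cells were 8.78% of the library with PBS and 20.1% with LPS as chosen, but 8.33% and 2.00% at resolution 0.5, 10.3% and 8.68% with each library clustered alone, and 11.3% and 6.31% with clustering without the response genes. Of 12 MHC class II and co-stimulation genes 6 were lower and 1 higher (median -0.96), such as H2-Aa (877 to 211 CPM, -2.05), beside a dendritic-cell-like share of 16.1% with PBS and 8.18% with LPS. Clusters 2, 4, 5 and 14 held most of these cells with LPS, and clusters 8 and 9 with PBS.

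With Reg3g against LPS, the highest genes in monocyte-like cells were the neutrophil collagenase Mmp8 (0.96), Hspa1b (0.94), Tnf (70.1 to 125 CPM, 0.83), Slc12a2 (0.74) and Pltp (0.71). Mmp8 stood at 308 CPM in neutrophil-like cells against 50.4 CPM here with Reg3g, so neutrophil RNA is not excluded for it. The lowest were Ly6i (165 to 83.1 CPM, -0.99), the chemokine Cxcl1 (-0.83), Ly6a (-0.75), H2-Q7 (-0.73) and Nfkbie (-0.70). All 24 cell cycle genes were lower (median -0.39), such as Cdk1 (-0.79), opposite in sign to the alveolar-macrophage-like cells. The list was also lower in neutrophil-like cells (15 of 15, median -1.28) and in lymphoid cells (16 of 18, median -1.395). Both classes held far fewer UMIs. In dendritic-cell-like cells the median was -0.04. The lower list was thus not particular to monocyte-like cells, and its cause was not tested. In the classical-like cells of the clustering as chosen, a split that moves with the settings, 22 of 24 were lower (median -0.22). They were 3452 of 6061 monocyte-like cells with LPS and 1980 of 4159 with Reg3g, and cluster 14, led by histone and cell cycle genes, held 450 and 218 of them. All 9 mitochondrially encoded genes were higher (median 0.47). S100a8 (401 to 729 CPM), a neutrophil gene that was set aside in these cells, stood at 313 and 1047 CPM in lymphoid cells of the same libraries.

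Interstitial-macrophage-like cells numbered 456, 153 and 128 in the PBS, LPS and LPS with Reg3g libraries, all in cluster 13. With LPS they held more Saa3 (4.36 to 11150 CPM, 11.32), Lcn2 (9.11, 7.25 to 12.16, from 2 counts), Acod1 (8.80, 6.30 to 14.12, from 1 count), Ccl5 (8.38) and Csf3 (7.22, 4.67 to 12.55, from 1 count), and less Retnla (-7.83, -13.14 to -5.35, down to 1 count), Mgl2 (-4.15), Mmp12 (-4.13), Egr3 (-4.10, -7.17 to -2.22, down to 2 counts) and Fabp1 (-3.93). Of 13 MHC class II and co-stimulation genes 8 were at least 2-fold lower and 1 higher, Cd274 (2.45), with a median of -1.63, beside a dendritic-cell-like share of 16.1% with PBS and 8.18% with LPS. With Reg3g against LPS the list was lower again, with 7 of 13 at least 2-fold lower (median -1.06). Examples were H2-DMb1 (145 to 42.2 CPM, -1.77) and H2-Eb1 (2340 to 948 CPM, -1.30). The share of dendritic-cell-like cells was lower in that library too. In the same comparison the list median was -0.04 in monocyte-like and 0.16 in lymphoid cells, but -0.69 in neutrophil-like cells. The lymphoid class mixes T-or-NK-like with B-cell-like cells, the latter 23 of 175 with LPS and 25 of 117 with Reg3g. This change of mix can move the lymphoid value, so it gives no clean background. The cause was not tested. The highest genes with Reg3g were Fn1 (1.75, 0.79 to 2.81), Mmp9 (1.68), Asph (1.62), Ctsk (1.60) and Leng8 (1.52). Mmp9 is also a leading gene of the neutrophil-like cluster, and the neutrophil genes S100a8 (173 to 502 CPM) and S100a9 (194 to 606 CPM), set aside in these cells, were higher too. The lowest were the cytokine subunit Il12b (32 counts to 0, at least 11.1-fold lower), Cd209f (-3.09), H2-M2 (-2.11), Arl5c (-2.05) and Zmynd15 (-1.95).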

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

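The values without the cycling cluster were chosen only after the result was seen. The cell cycle list differed in sign between classes under the same comparison of LPS with PBS: its median log2 ratio was -2.12 in alveolar-macrophage-like and 2.62 in monocyte-like cells. In alveolar-macrophage-like cells 23 of 23 measured members were lower with LPS, and in monocyte-like cells 24 of 24 were higher. The difference between the classes was not tested, since each group has 1 library. Without cluster 16, the cluster of alveolar-macrophage-like cells led by cell cycle genes, the median in these cells was -0.05. In monocyte-like cells cluster 14, led by histone and cell cycle genes, held 11 of 2189 cells with PBS and 450 of 6061 with LPS, and the median without it was not computed. With Reg3g against LPS the signs were the other way round, at 0.42 and -0.39. In that comparison the list was also lower in neutrophil-like cells (median -1.28) and in lymphoid cells (median -1.395). No technical or biological explanation was tested for this pattern.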

How the results depend on the processing

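Values with clusters weighted as in the LPS library, those without the cycling cluster and the shares of other classes were chosen after the data were seen. No paired analysis was possible because each group has 1 library. In alveolar-macrophage-like cells the 20 genes named for LPS against PBS kept their sign in all 260 alternative values and moved outside the counting interval in 60. The 20 for Reg3g against LPS kept theirs in 260 and moved in 25. Sizes were less stable for some genes. For Reg3g against LPS, Klf2 ranged from -0.988 to -0.18, Cxcl10 from -0.65 to -0.061 and Trib1 from 0.202 to 0.598, but Ybx3 only from 0.495 to 0.575. For LPS against PBS, Ccl17 ranged from 2.04 to 8.83 and Sdc4 from 3.86 to 10.58, but Cxcl3 only from 8.43 to 8.95. The share of alveolar-macrophage-like cells became 50.3%, 43.6% and 48.2% (PBS, LPS, LPS with Reg3g) under the stricter cell filter, 36.1% and 42.5% (LPS, LPS with Reg3g) without a filter, 43.9%, 36.1% and 42.6% without doublet removal, and 39.7% (LPS) with doubled removal. The LPS library stayed lowest in each of the 8 alternatives where all 3 had a value. The interferon median for LPS against PBS was 0.98 over all cells, and for Reg3g against LPS 0.013 with weighted clusters, where its sign changed. The chemokine median for Reg3g against LPS was 0.01 with a floor of 5 CPM. The cell cycle median for LPS against PBS was -1.33 with thinned cells, -0.49 over all cells and -0.048 without the cycling cluster. For Reg3g against LPS it was -0.21 over all cells, 0.19 without the cycling cluster and 0.17 with weighted clusters, and for Reg3g against PBS 0.12 without the cycling cluster. Leaving out that cluster removes a group of cells led by cell cycle genes, and all cells together mix the classes. The cause of these changes was not tested. The NF-kB median for Reg3g against LPS kept its sign in 17 alternatives (-0.17 to -0.08).

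Other list medians changed sign as follows. Under median-of-ratios scaling the inflammasome list was 0.18 (LPS against PBS) and 0.032 (Reg3g against PBS), autophagy 0.13, -0.044 (Reg3g against LPS) and 0.14 (Reg3g against PBS), and oxidative stress -0.023 (Reg3g against LPS). Under trimmed mean scaling the inflammasome list was 0.19 and 0.045, autophagy 0.13, -0.036 and 0.16, oxidative stress -0.015, phagocytosis 0.009 (from -0.29) and LPS sensing 0.0 (from -0.30; both Reg3g against PBS). Over all cells the inflammasome list was 0.50 and 0.38, with a floor of 5 CPM 0.089 and 0.12, and with a floor of 50 CPM 0.35 and 0.20. With that floor LPS sensing was 0.46 (from -0.36) and 0.56 (from -0.30) and autophagy -0.009 (Reg3g against LPS). MHC class I for Reg3g against LPS was 0.033 without carry-over genes and 0.095 with weighted clusters, which gave -0.005 for alternative activation and -0.019 for autophagy. Autophagy for Reg3g against LPS was also 0.0 without a filter, -0.001 with the stricter filter, -0.003 at resolution 0.5, -0.002 with libraries clustered alone, -0.004 without response genes and -0.025 with thinned cells. The cause was not tested. Interstitial-macrophage-like cells held 567603 UMIs in the LPS and 592004 in the LPS with Reg3g library and lymphoid cells 543882 and 415655, against 30930896 and 31544928 in alveolar-macrophage-like cells.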

Other observations

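The tests in the last 3 paragraphs were written before their results were seen, but weighting the clusters was chosen as an alternative for the lists after the data were seen. Dendritic-cell-like cells, 1265, 1064 and 254 in the PBS, LPS and LPS with Reg3g libraries, were not part of the planned comparisons. With LPS against PBS their highest genes were the myosin kinase Mylk (1.59 to 51.6 CPM, log2 ratio 5.02), the interferon-induced GTPase Gbp5 (4.57), Fabp5 (4.29), the co-stimulatory receptor Tnfrsf9 (4.22) and Ly6a (4.06). Among their lowest were Retnla (741 to 2.26 CPM, -8.36), Fcrls (-7.88, -13.19 to -5.39, down to 1 count), Lyz1 (-5.28) and the type 2 marker Cd209a (-3.12). Of 30 interferon response genes 22 were at least 2-fold higher (median 1.65). The inhibitory ligands Pdcd1lg2 (4.13 to 48.2 CPM, 3.54) and Cd274 (23.9 to 152 CPM, 2.67) were higher too. The mix of the 3 dendritic-cell-like classes differed between PBS (681 type 1, 476 type 2 and 108 migratory cells) and LPS (298, 230 and 536). The migratory class was the largest with LPS and also with LPS and Reg3g (68, 50 and 136).

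With Reg3g against LPS, dendritic-cell-like cells held less Cxcl9 (67.2 to 19.6 CPM, -1.78), Nr4a2 (-1.07), Mgl2 (-0.95), Flrt3 (-0.94) and Rsad2 (-0.92), and more Scin (0.83), Tgm2 (0.75), Lpcat1 (0.75), Ybx3 (0.74) and Tmem39a (0.74). Of 30 interferon response genes 23 were lower, none by 2-fold (median -0.18). Of 17 glycolysis and hypoxia genes 10 were higher (median 0.02). In monocyte-like cells 8 of 18 glycolysis and hypoxia genes were at least 2-fold higher with LPS than with PBS (median 0.87), such as Gapdh (465 to 1427 CPM, 1.62), and the complement gene C1qb stood at 30.0 and 933 CPM (4.96).

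Alveolar-macrophage-like cells given Reg3g with LPS lay slightly closer to PBS across genes than those given LPS alone. Counting noise of the shared LPS library is argued against, since with the LPS cells split into 2 parts the slope was -0.0939 (-0.102 to -0.0858), beyond the -0.02 set for noise. Weighting the clusters as in the LPS library left 51.5% of the slope, between the bounds set for and against another mix of clusters, so a different mix may account for part of it. Differences between pools of mice or preparations cannot be told apart from an effect of Reg3g, because each group has 1 library. The LPS with Reg3g library also lay between PBS and LPS in technical measures. In the order PBS, LPS with Reg3g, LPS, barcodes were 8475, 10213 and 15015. In alveolar-macrophage-like cells, median UMIs were 7665, 7545 and 6047, and median mitochondrial shares 0.72%, 0.486% and 0.379%. Whether these account for the slope was not tested. An effect of Reg3g stays open as a hypothesis.

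Dendritic-cell-like cells made up a smaller share of the library with Reg3g than with LPS alone. A shift in the cells kept by the filter is argued against, since without a cell filter the ratio of shares was 0.352. A stricter F4/80 gate may have removed dendritic cells, and the log2 ratio of Adgre1 in those that remained was 0.559 (-0.001 to 1.097). That interval reaches 0, so a stricter gate cannot be told apart from fewer dendritic cells in the lung, which stays open and untested.

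S100a8 was higher in monocyte-like cells with Reg3g than with LPS alone, at 729 against 401 CPM, and S100a9 at 293 against 200 CPM. Free RNA from neutrophils is a candidate explanation: S100a8 was also higher in lymphoid cells (log2 ratio 1.74, 1.48 to 2.01), and neutrophil-like cells held more of it (18790 against 7951 CPM). Their share was 1.95% against 1.38%, but 1.02% against 1.11% under the stricter cell filter. Doublets of neutrophils and monocytes are argued against, since with 2 times as many high-scoring cells removed the log2 ratio was 0.944. Higher expression in the monocytes themselves stays open.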
